A study of Mus musculus with 2 samples.

How the data were processed

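The series measured RNA of isolated nucleoli from RAW 264.7 cells, a mouse macrophage line, in 2 samples: 1 from unstimulated cells and 1 from cells exposed to lipopolysaccharide (LPS), a bacterial cell wall component, at 80 ng/ml for 12 h. Per the labels' protocols, nuclei were sonicated, nucleoli were pelleted through sucrose, ribosomal RNA was depleted with a Ribo-Zero kit, and random-primed libraries with a dUTP-marked second strand were sequenced on an Illumina HiSeq 2000. Per the submitters' processing notes, Trimmomatic 0.32, FastQC and the mouse build mm10 were used. The aligner, the program that gave a value per gene, its annotation and any filter on genes are not given in the sources used here.

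The deposited data were 2 tables, and each held 2 sets of values rather than those of the 1 sample it was listed under. The first has no header and lists 20220 gene symbols, each with 2 values, the same values plus 1, and a ratio. The ratio deposited by the authors equals the second value plus 1 divided by the first value plus 1, tested in all 20220 rows to a relative tolerance of 1e-09. The second table gives FPKM per RefSeq transcript in 2 columns named No2_FPKM and No3_FPKM, per the file headers, and it was not used. No label ties any of these 6 columns of values per library to the unstimulated or the LPS sample, so none of the 6 was given to a sample, and none was used as a measurement. What was analysed is the authors' ratio alone. The value on top is called the numerator and the other the denominator below, and which of them came from the LPS sample is not stated by the table and was not inferred.

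This departs from the plan fixed before the data were examined, which assumed values per library. Levels, RNA class shares, the correlation of the libraries, filters on low values and random lists matched on expression were planned and were not computed, since they use the columns set aside. The number of reads behind each gene is unknown, so no counting interval or detection floor is given. There was 1 library per condition, so no test between conditions was possible and no p-value is given. The 1 added to both values draws the ratio of a weakly expressed gene towards 1, so a ratio understates the change of such a gene.

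The ratio was taken to the log2 scale. A ratio within 1e-09 of 1 was set aside, since it means equal values and is what a gene at 0 in both columns would give. A fixed rule of size counted genes with a ratio of at least 2 or of at most 0.5. The 29 gene lists were fixed before the data were examined, and 16 had at least 5 genes with a ratio other than 1. Each such list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from the other genes with a ratio other than 1, and again among 10000 lists matched on transcript length in 10 bins. These percentiles describe this one comparison, and genes are not replicates. They are not matched on expression, so a list of well-expressed genes, whose ratios are less drawn towards 1, reaches an extreme more easily. The 95% interval of a list's median comes from the binomial order statistics of its genes and covers the spread between genes only. On simulated data made from the 12372 genes, 3.5% of 200 unshifted lists of 20 genes fell outside the central 95% of random lists, and 100.0% of 50 lists shifted by 0.5 on the log2 scale fell above it. Fewer than 10000 random lists were used there. The simulated lists were drawn at random from the same genes, and each member got the full shift. They check the procedure only, not lists of genes that are expressed together or strongly.

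The genes named are the 12 with the highest and the 12 with the lowest ratio, the 3 members of each list with the largest absolute log2 ratio, and a fixed set of inflammatory and nucleolar genes. Other genes were named outside this rule, after their values were seen. They are, among genes with a ratio other than 1, the lowest of some lists (Il10, Rela, Irf1, Fosb). They also include exceptions in a list (Hist1h4m, H1f0, Hist2h2be, Hist2h3c1, Hist2h2aa2, Ccnd2) and the ends of a range (Hfe, Prss16, Cd79b). The rest are other neighbours labelled in a figure (Zfp184, Zfp322a, Abt1, Trim38), the single measured member of a list (Lars2), a paralog (Lilrb4) and a gene with a long transcript (Hist1h1d). The planned minimum level for a named gene was not applied, and the genes with the highest level in each library were not named, since both use the columns set aside. Symbols were matched to RefSeq (GRCm38.p6) and GENCODE M21, both on GRCm38, the assembly that mm10 denotes, by current symbol or a unique synonym. Of the 20220 symbols, 20154 matched, 20092 had a single GENCODE position and 20115 a transcript length, taken as the longest GENCODE transcript. Sequence shared between histone genes and any other gene was measured as the share of 31-base words of a gene's GENCODE transcripts that also occur in another gene's transcripts. The alternatives planned for the ratio were division by its median and a 4-fold rule. Leaving out histone genes, leaving H1f0 out of the histone list, keeping genes with a ratio of 1 in the lists, and length-matched random lists were added after the data were seen, the last before its own results were known. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.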

Results

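Nucleolar RNA of RAW 264.7 mouse macrophages was sequenced from 1 unstimulated culture and 1 culture exposed to LPS for 12 h, to compare nucleolar RNA in the absence and presence of LPS. Neither of the 2 samples was of whole cells or another fraction. A difference particular to nucleoli therefore cannot be told apart from one in the RNA of the whole cell. The comparison available gene by gene was the ratio in the authors' deposited table, which does not name the condition on top. All directions are therefore given as towards the numerator (a ratio above 1) or towards the denominator (a ratio below 1). There were no replicates and the read depth was unknown, so no gene has an error and no difference could be set against the spread between replicates.

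The table listed 20220 genes, of which 19793 had a RefSeq gene type. Of these, 19732 (99.7%) were protein-coding. The lists of box C/D and H/ACA snoRNAs, scaRNAs, spliceosomal snRNAs, RNA polymerase III transcripts, ribosomal RNA, microRNAs and mitochondrial transcripts matched 0 of its symbols. The deposited table of transcripts does list names of 67 box C/D snoRNAs, 35 H/ACA snoRNAs and 9 scaRNAs, but its values, which no label ties to a sample, were set aside, so the small RNAs typical of nucleoli were not analysed here. The ratio was 1 for 7848 genes, above 1 for 5342 and below 1 for 7030. Over the 12372 genes with a ratio other than 1, the median log2 ratio was -0.05, with quartiles at -0.33 and 0.17. The ratio was at least 2 for 428 genes (3.46%) and at most 0.5 for 444 genes (3.59%).

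The numerator end was led by inflammatory genes and the denominator end by histone genes. Of the 12 genes with the highest ratio, 7 belonged to the list of LPS-induced cytokines and chemokines and 2 to the list of inflammatory enzymes and effectors. In the authors' deposited table, the highest ratios were 119.8 for Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, 119.5 for Il1b, the cytokine interleukin-1 beta, and 97.2 for Irg1, the itaconate-producing enzyme. Next in the authors' deposited table came Ccl4 at 73.5, Csf3 at 49.97, Cxcl2 at 48.4, Ccl5 at 47.0, Ccl3 at 38.6, Spp1 at 33.0, Ccl22 at 32.1, Ifi202b at 23.1 and Gp49a at 22.9. Gp49a has a close paralog, Lilrb4, with a ratio of 8.81 in the authors' deposited table, and reads could be split between them. Of the 12 genes with the lowest ratio, 11 were histone genes. The exception was Trem2, a lipid-sensing receptor of macrophages, with a ratio of 0.116 in the authors' deposited table.

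On GRCm38, Ptgs2 lies on chromosome 1 from 150100031 to 150108227, Il1b on chromosome 2 from 129364570 to 129371139 and Irg1 on chromosome 14 from 103046977 to 103056573. Ccl5 (83525778 to 83530518), Ccl3 (83647844 to 83649355) and Ccl4 (83662584 to 83664683) are neighbours on chromosome 11. Trem2 lies on chromosome 17 from 48346401 to 48354147. The ratio was given per gene, so exons, introns and UTRs of these genes were not told apart.

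**Figure D1:**
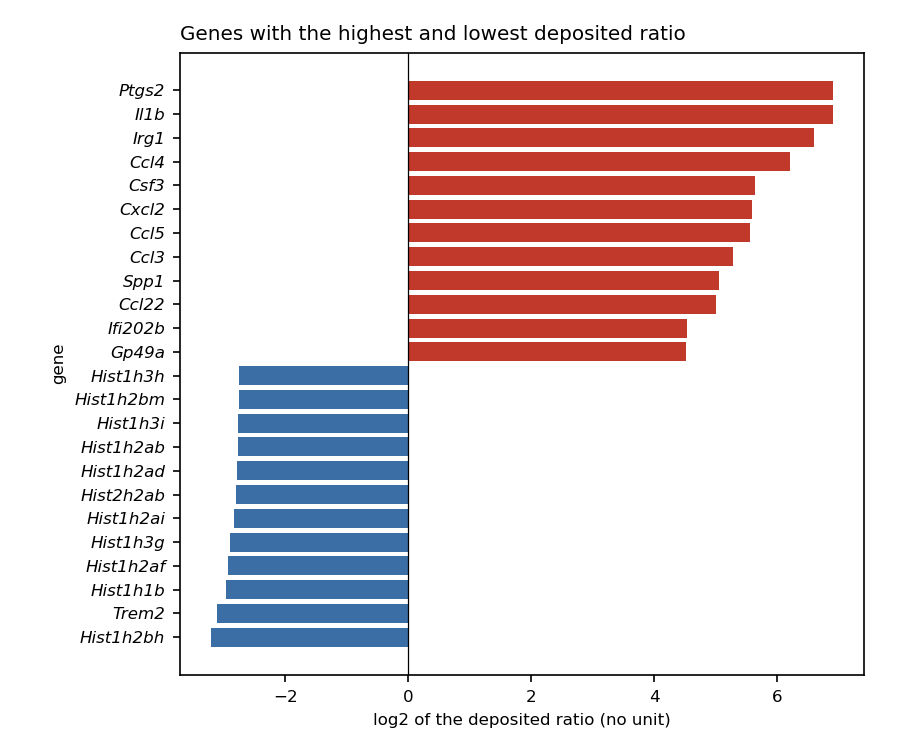
Horizontal bars give the log2 of the deposited ratio (no unit, 1 value per gene, no error available) for the 12 genes with the highest and the 12 with the lowest ratio. Of the 12 highest, 9 are on the cytokine or effector lists, led by Ptgs2 (6.90) and Il1b (6.90), and 3 (Spp1, Ifi202b and Gp49a) are on no list, while 11 of the 12 lowest are histone genes, down to -3.21 for Hist1h2bh.

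Cytokine and chemokine genes that LPS is known to induce in macrophages lay towards the numerator. All 23 list members with a ratio other than 1 were above 1, and 19 were at least 2, with a median ratio of 9.33 (log2 3.22, 95% interval over genes 1.80 to 5.00). None of 10000 random lists had a median as high. Besides the chemokines above, the authors' deposited table gave Cxcl10, an interferon-induced chemokine, 12.3 and Tnf, tumour necrosis factor, 4.32. The lowest of these 23 was the anti-inflammatory interleukin Il10, at 1.08 in the authors' deposited table. The list had 27 genes in that table, and those outside the 23 had a ratio of 1.

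Inflammatory enzymes and effectors had a median ratio of 2.22 (log2 1.15, interval 0.47 to 2.28), with 13 of 24 at 2 or more and 24 above 1. After Ptgs2 and Irg1, the authors' deposited table gave 13.8 for Lcn2, an iron-withholding protein, and 5.37 for Nos2, the inducible nitric oxide synthase. NF-kB subunits and feedback inhibitors had a median of 2.71 (log2 1.44, interval 0.97 to 1.93), with 17 of 24 at 2 or more. Here the authors' deposited table gave 15.3 for Socs3, a suppressor of cytokine signalling, 11.6 for Ier3, 5.87 for the phosphatase gene Dusp2 and 3.35 for Nfkbia, which encodes the NF-kB inhibitor IkB alpha. The lowest of the list was Rela, the NF-kB subunit p65, at 1.15 in the authors' deposited table. None of 10000 random lists had a median as high as either of these lists.

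Interferon-stimulated genes also lay towards the numerator. Of 41 measured members, 30 had a ratio of at least 2 and 41 were above 1, with a median of 3.93 (log2 1.98, interval 1.36 to 2.36), and none of 10000 random lists had a median as high. The authors' deposited table gave 17.01 for Rsad2, which encodes the antiviral protein viperin, 13.1 for Ifi44 and 12.2 for Oasl1, an oligoadenylate synthetase-like gene. The lowest of these 41 was Irf1, an interferon regulatory factor, at 1.08 in the authors' deposited table. Of the 42 listed genes in that table, those outside the 41 had a ratio of 1. Together the 4 inflammatory and interferon lists held 112 genes with a ratio other than 1, and 79 of the 428 genes at 2 or more.

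Immediate early genes, the transcription factors first induced by many stimuli, went both ways: 5 of 18 were at 2 or more, 10 were above 1 and 8 below. Their median was 1.23 (log2 0.30, interval -0.28 to 1.02), and 4 of 10000 random lists had a median as high. The authors' deposited table gave Nr4a1 3.12, Atf3 3.07 and Fosl1 2.33, and the lowest of the list was Fosb at 0.508.

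Genes of the histone list lay towards the denominator. The list was drawn by symbol to hold replication-dependent histone genes, which are expressed in S phase. It also matches H1f0, a replacement linker histone, and its other members were not checked singly for being replication-dependent. Of 62 measured members, 61 had a ratio below 1 and 55 a ratio of 0.5 or less, with a median of 0.205 (log2 -2.29, interval -2.53 to -2.10), and none of 10000 random lists had a median as low. Without H1f0, 60 of 61 were below 1 and the median was 0.204 (log2 -2.29, interval -2.53 to -2.10). Genes of the list made up 39 of the 50 lowest genes of the table. The histone types shared this position, with median ratios of 0.152 over 15 H2A genes, 0.206 over 17 H2B genes, 0.197 over 11 H3 genes, 0.237 over 13 H4 genes and 0.370 over 6 linker histone (H1) genes, or 0.259 over 5 without H1f0. In the authors' deposited table, the lowest ratios were 0.108 for Hist1h2bh, 0.128 for Hist1h1b and 0.131 for Hist1h2af. H1f0 stood at 0.902 in the authors' deposited table. Hist1h4m went the other way, at 5.69 in the authors' deposited table. Histone genes share much of their sequence, with a median of 55.8% of 31-base words found in another gene, so values of single histone genes are uncertain.

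Of the 62 histone genes, 50 lie on chromosome 13 between 21715763 and 23934156. Inside the same stretch, 6 other genes had a ratio other than 1, with a median log2 ratio of 0.03 (interval -0.43 to 0.23). In the authors' deposited table these ranged from 0.743 for Hfe, an iron regulator, to 1.17 for Prss16. Histone genes on other chromosomes, 12 in number, had a median log2 ratio of -1.52 (interval -2.10 to -0.15). Without H1f0, the other 11 had a median of -1.67 (interval -2.25 to -0.0005).

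**Figure D2:**
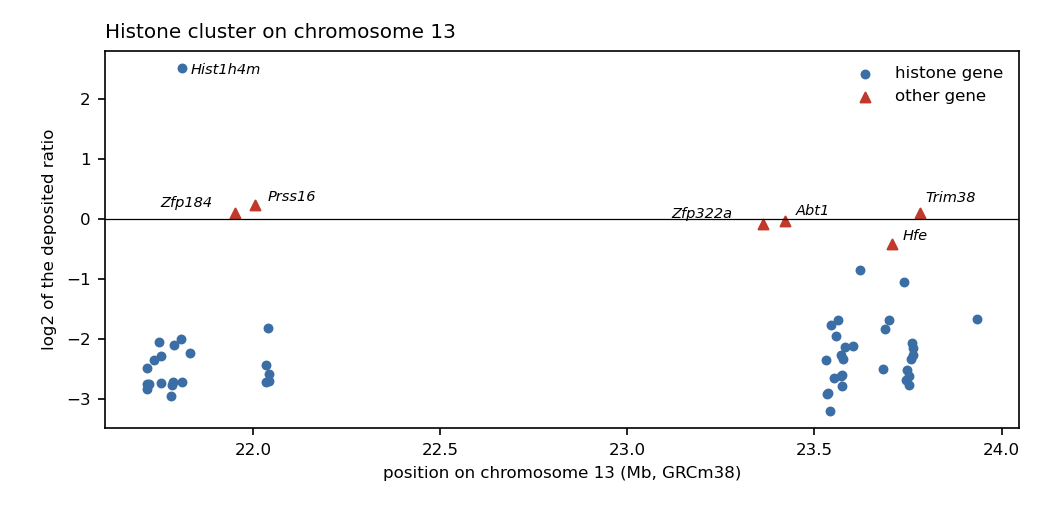
Each point is a gene with a ratio other than 1 in the histone cluster on chromosome 13 (x axis, position in Mb on GRCm38; y axis, log2 of the deposited ratio, no unit). Circles are the 50 histone genes, at -0.85 or lower except Hist1h4m at 2.51, and triangles are the 6 other genes, between -0.43 and 0.23.

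Cell cycle genes lay on the same side as the histone genes. Of 32 measured members, 31 had a ratio below 1 and 19 a ratio of 0.5 or less, with a median of 0.455 (log2 -1.14, interval -1.32 to -0.90), and none of 10000 random lists had a median as low. The authors' deposited table gave 0.194 for Mki67, the proliferation marker Ki-67, 0.268 for Top2a, a topoisomerase of dividing cells, and 0.288 for Ccna2, which encodes cyclin A2. The member above 1 was Ccnd2, a cyclin D gene, at 1.37 in the authors' deposited table.

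Genes for nucleolar proteins and ribosome assembly were lower in the numerator by less. Of 59 ribosome biogenesis genes, 57 had a ratio below 1 and 6 a ratio of 0.5 or less, with a median of 0.682 (log2 -0.55, interval -0.65 to -0.48). None of 10000 random lists had a median as low. Those random lists were not matched on expression, and some other families, picked after their values were seen, lay near this level. The median log2 ratio was -0.64 for nucleoporin genes (Nup) and -0.48 for Ndufb genes, while Psma and Psmd genes lay at 0.07 and 0.05. The count of random lists therefore does not set the biogenesis list apart from families such as Nup. The authors' deposited table gave 0.403 for Ubtf, a transcription factor of RNA polymerase I, 0.415 for Gnl3, which encodes nucleostemin, and 0.423 for Ncl, which encodes nucleolin. Npm1, the gene of nucleophosmin, stood at 0.571 and Fbl, the gene of the snoRNA-associated methyltransferase fibrillarin, at 0.891 in the authors' deposited table.

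Cytoplasmic ribosomal protein genes had a median of 0.820 (log2 -0.29, interval -0.34 to -0.17), with 60 of 79 below 1, and 0 of 10000 random lists were as low. Of these, 1 was at 0.5 or less, Rplp2 at 0.416 in the authors' deposited table. The random lists were not matched on expression, and some other gene families, picked after their values were seen, lay near this level. The median log2 ratio was -0.27 for Eif genes (43 of 53 below 1) and -0.35 for Mrps genes (24 of 29). Psma and Psmd genes lay at 0.07 and 0.05. The count of random lists therefore does not set the ribosomal protein list apart from families such as Eif and Mrps. The 14 measured snoRNA host genes had a median of 0.737 (log2 -0.44, interval -0.94 to -0.09), and 20 of 10000 random lists were as low. None of the list's Snhg genes, Gas5 or Zfas1 is among these 14, and 9 of the 14 also stand on other lists. Their largest departures in the authors' deposited table were 2.71 for Nfkb1, 0.423 for Ncl and 0.520 for Wdr43. Genes of nuclear speckle, splicing and paraspeckle proteins were below 1 in 28 of 28 cases, with 3 at 0.5 or less and a median of 0.659 (log2 -0.60, interval -0.73 to -0.34). None of 10000 random lists was as low, but these were not matched on expression either. Nup genes, with a median log2 ratio of -0.64, lay near this level, so the count does not set the splicing list apart from them. The authors' deposited table gave 0.364 for the splicing factor gene Srsf2, 0.461 for Sfpq, a paraspeckle protein gene, and 0.484 for Srsf7.

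Other lists lay near the middle of the table as a whole. Myeloid and macrophage identity genes went both ways, with 6 of 25 at 2 or more, 3 at 0.5 or less and a median of 1.01 (log2 0.01, interval -0.26 to 0.49), a median that 2018 of 10000 random lists matched or exceeded. In the authors' deposited table, the scavenger receptor gene Msr1 stood at 8.88 and Cd53 at 3.57, against 0.116 for Trem2. Stress response genes had a median of 1.07 (log2 0.10, interval 0.01 to 0.59), and 472 of 10000 random lists were as high, with Ddit3 at 2.09, Asns at 1.90 and Gclc at 0.528 in the authors' deposited table. Glycolysis genes had a median of 1.00, whose side of 1 depends on the scaling, and abundant cytoplasmic housekeeping genes a median of 0.965, both inside the central 95% of random lists. Within these, the authors' deposited table gave the glucose transporter gene Slc2a1 2.60, Hk3 2.12 and Pgk1 1.52, and the tubulin genes Tubb5 0.399 and Tuba1b 0.489 against 1.90 for B2m, the light chain of MHC class I.

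Markers of other cell types gave few values. Of the lists for T, B, fibroblast, epithelial and erythroid cells, 2, 2, 5, 1 and 1 genes had a ratio other than 1. In the authors' deposited table these ranged from 0.855 for the collagen gene Col3a1 to 1.18 for the B cell receptor gene Cd79b. The fibroblast list had a median of 0.944 (log2 -0.08, range -0.23 to 0.02). From the list of nuclear long non-coding RNAs and associated loci, 1 gene was present, Lars2, a mitochondrial tRNA synthetase gene, at 1.82 in the authors' deposited table.

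**Figure D3:**
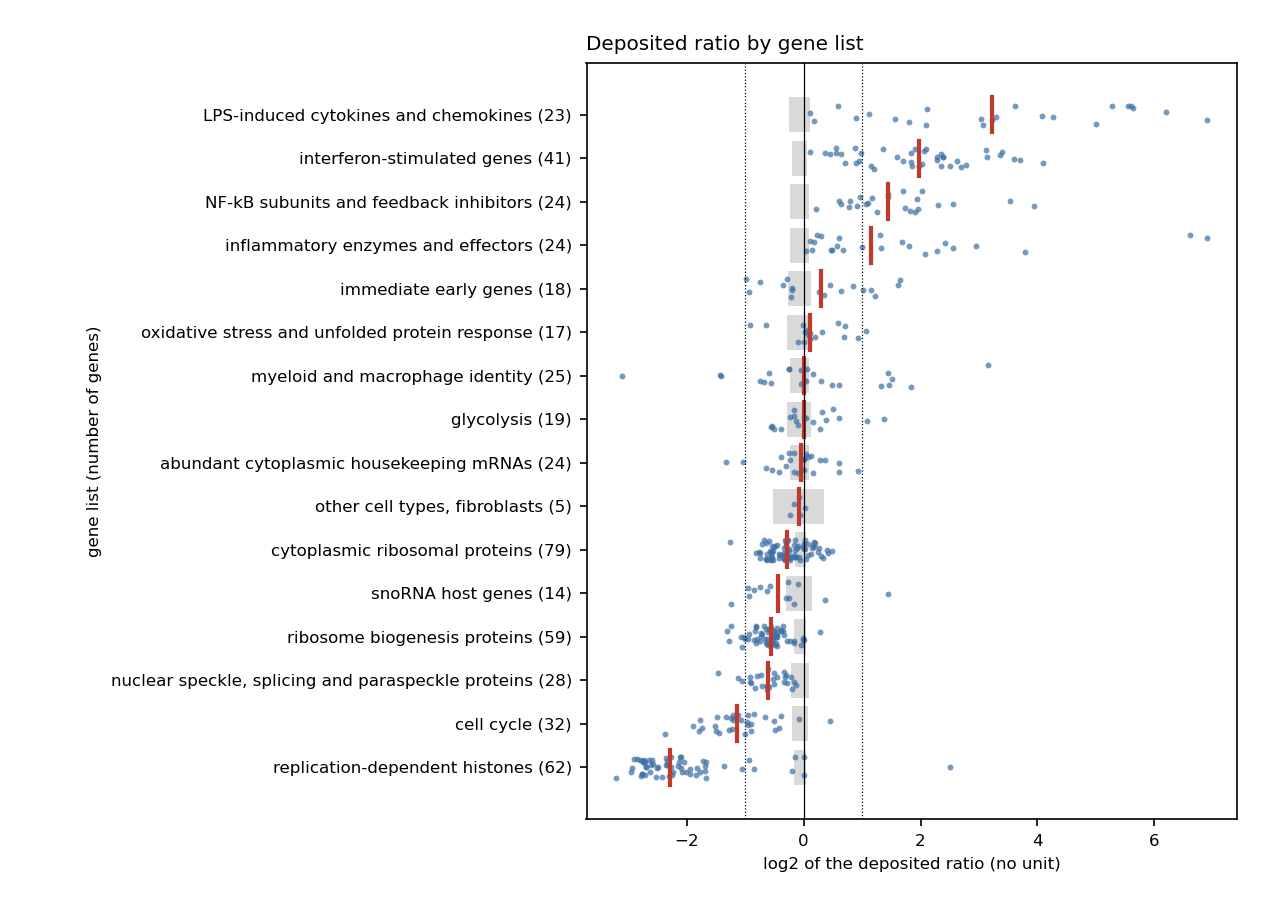
Each point is a gene with a ratio other than 1 (x axis, log2 of the deposited ratio, no unit), in rows by gene list with the number of genes; points are spread vertically for legibility. Red lines are list medians, grey bands hold the central 95% of medians of random lists, and dotted lines mark ratios of 0.5 and 2. The cytokine list has the highest median (3.22) and the histone list the lowest (-2.29).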

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

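Dividing every ratio by the median ratio of genes other than 1 (0.968), planned before the data were examined, adds the same amount to every log2 ratio. It can therefore change the sign only of a median just below 0, as in the glycolysis list, whose median went from -2.2e-05 to 0.05, and the signs kept elsewhere are no test of the lists. The division took the genes at 2 or more from 428 to 466 and those at 0.5 or less from 444 to 393, and Tuba1b from -1.03 to -0.98, short of the 2-fold rule. With 4-fold in place of 2-fold, 111 genes lay towards the numerator and 56 towards the denominator, against 428 and 444, and histone genes were 43 of the 56 but 55 of the 444. Settings added after the data were seen (histone genes left out of the counts, H1f0 left out of the histone list, genes with a ratio of 1 kept in the lists) moved no count by over 1.5 times and no median beyond its interval. Random lists matched on transcript length moved the number of lists as low as the cytoplasmic ribosomal protein list from 0 to 8 of 10000, and for the snoRNA host list from 20 to 28. No paired analysis was possible because each condition has 1 library. Other settings fixed beforehand (another pseudocount, filters on low values, upper-quartile scaling, genes missing from a table, removal of non-coding RNA, RNA class shares, correlation of the libraries) were not run, since they use the columns of values that no label ties to a sample, which were set aside. No gene name was listed more than once, so merging rows changed nothing. Read depth was unknown, so what depth limits could not be stated gene by gene.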

Other observations

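Gene families were also grouped by the letters before the first digit of the symbol, a grouping made after the data were seen, which gave 215 stems with at least 8 genes with a ratio other than 1. They overlap the fixed lists, which hold 4 of 9 Gbp, 1 of 12 Parp and 5 of 28 Polr genes, and so are not independent of them. The families given here were picked after their values were seen, by no fixed rule. The guanylate-binding protein genes (Gbp), interferon-induced GTPases, were above 1 in 9 of 9 cases with a median ratio of 1.29 (log2 0.37, 95% interval over genes 0.12 to 0.66). Proteasome beta subunit genes (Psmb) were above 1 in 10 of 11 cases, with a median of 1.24, but the other proteasome stems went both ways, with 4 above and 4 below 1 for Psma (median 1.05) and 7 and 7 for Psmd (median 1.04). Of 12 ADP-ribosyltransferase genes (Parp), 5 had a ratio of at least 2 and 8 were above 1, but 4 were below 1, and the interval of their median log2 ratio (-0.26 to 1.49) spans 0. Of 8 schlafen genes (Slfn), 3 had a ratio of at least 2, 5 were above 1 and 3 below, and the interval (-0.26 to 3.97) also spans 0. On the other side, nucleoporin genes (Nup) were below 1 in 19 of 21 cases with a median of 0.643 (log2 -0.64, interval -0.89 to -0.45), RNA exosome genes (Exosc) in 10 of 10 with a median of 0.732, RNA polymerase subunit genes (Polr) in 24 of 28 with a median of 0.749, and mitochondrial ribosomal protein genes in 24 of 29 with a median of 0.784 for the small subunit (Mrps) and in 40 of 47 with a median of 0.842 for the large subunit (Mrpl). The families were not placed among random lists.

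The tests of scale for the cytokine genes, of histone genes on other chromosomes, of histone genes with little shared sequence against random lists and of the cell cycle list were chosen after the result was seen. Histone genes at the low end of the ratio: transcript length over the histone length range (381 to 2505 bases) is argued against. The 3832 non-histone genes in that range had a median log2 ratio of -0.062 (interval -0.08 to -0.04) against -2.29. Among random lists matched on length in 10 bins, 0 of 10000 were as low as the histone list. The range is wide and the genes were not matched on expression, so the shortest transcripts taken alone stay open. Low ratios were not confined to the chromosome 13 cluster. Without H1f0, a replacement histone, the 11 histone genes elsewhere had a median of -1.67 and stood at percentile 0.0, with 0 of 10000 random lists as low. The interval of their median ran up to -0.0005, with Hist2h3c1 and Hist2h2aa2 near 0. A lower signal over the whole cluster could reach these 11 only through shared reads, and they were not selected for little shared sequence. They therefore do not test such a signal for the genes inside the cluster. There it stays open, because the 6 other genes in the cluster (median 0.027) are few and may be drawn towards 1 by the added 1. Reads shared between near-identical copies are argued against as the cause only for genes whose reads fall on little shared sequence. Without H1f0, the 5 histone genes with under 10% of shared 31-base words had a median of -1.95 and stood at percentile 0.0, with 0 of 10000 random lists as low. They ranged from -2.96 for Hist1h1b to -0.19 for Hist2h2be. The share was taken over all transcripts of a gene, so a long transcript can dilute a shared stretch. The median gene, Hist1h1d, has a longest transcript of 7425 bases, against 743 for Hist1h1b. For genes with such long transcripts, and for genes that share more, shared reads stay open. The bound set before the result was seen, -1, was passed by the median over all 6 genes under 10% (-1.83) but not by its interval (-2.96 to -0.15). The upper end of that interval is H1f0, and without H1f0 it is Hist2h2be. Differences in LPS exposure, in RNA capture or in library preparation were not tested, since the table does not name its columns.

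Cytokine and chemokine genes at the high end of the ratio: a difference in scale between the columns would move every gene alike and is argued against as the whole cause, since the 24 abundant cytoplasmic housekeeping genes had a median log2 ratio of -0.051 (interval -0.31 to 0.13) against 3.22 (interval 1.80 to 5.00). Transcript length is argued against, since the list stood at percentile 100 among length-matched random lists. Reads shared between neighbouring paralogs stay open. With the lowest gene kept per stretch of genes under 1000000 bases apart, the list stayed at percentile 100 (18 genes, median log2 ratio 2.58). The position of the list thus did not rest on counting neighbours more than once. A kept gene could still hold reads of a removed neighbour, and shared sequence was measured for histone genes only. Expression level stays open as a contributor to the percentiles, because the random lists were not matched on it. The biological difference the design names, LPS exposure, stays open and untested here, because assigning the numerator from these genes would assume the answer.

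Cell cycle genes and histone genes at the same end of the ratio: the cell cycle list, which holds no histone genes, stood at percentile 0.0 among length-matched random lists, with 31 of 32 genes below 1. That value is the pattern itself, so it does not test a lower share of dividing cells behind the numerator column against lower transcript levels in each cell, and the 2 cannot be told apart here.

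Hist1h4m, named after its value was seen, stood at 5.69 while the other 12 H4 genes were at 0.5 or less, and 91.7% of its 31-base words occur in another gene. Hist2h3c1 and Hist2h2aa2, with 100% of their words found in another gene, had ratios of 0.9996 and 1.000.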
